A study of Canis lupus familiaris with 2 samples.

How the data were processed

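Poly-A-selected RNA from CLBL-1 and CLBL-1 8.0 cells was sequenced, with RNA taken from 3 dishes of cells, per the labels' protocols. Whether the dishes were pooled is not given in the sources used here. The labels put 1 sample in each group, the parental line and the doxorubicin-resistant line maintained in 8 µM doxorubicin, and both lines were grown with 10% fetal bovine serum. The column of the resistant line has a shortened name, CLBL-8, which matches the label of CLBL-1 8.0 and of no other sample.

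HISAT2, StringTie and the CanFam3.1 dog genome build were used, per the submitters' processing notes. Their versions, settings, annotation and strand handling are not given in the sources used here. The abundance values in the deposited comparison table are per gene and per line, are not whole numbers and have no stated unit: they may be FPKM or TPM, and the listed values summed to 120585 in the resistant line and 111082 in the parental line, with medians of 17.7 and 13.4. Because the file holds selected genes, these sums are not library totals, the depth per sample is unknown and no counting interval was computed. The log2 fold changes in the deposited table are by the authors, per the file headers. They equal log2 of the resistant over the parental value without a pseudocount to within 1.6e-14, and 1720 rows have a finite value. The rule by which the authors selected rows is not given in the sources used here; in the values, the smallest absolute log2 fold is 0.67, the smallest larger value is 5.01 and the smallest difference is 2.00. The p-value of each ontology or pathway term is the authors', per the file headers, and its tool, background and adjustment are not given in the sources used here. The number of genes per term was also taken from the deposited tables, which held 118 ontology and 50 KEGG terms.

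All 1729 rows were used. They carry 1727 distinct symbols, 257 placeholder names that begin with LOC, and 22 rows have no gene ID. A reference table of dog genes, assembly UU_Cfam_GSD_1.0, served only for names, for which genes neighbour or overlap each other and for chromosome assignment, and none of its coordinates are printed. Of 1707 gene IDs, 1605 were found in it, 1573 of them with the same symbol, and 6 rows lie on another chromosome than the gene of that ID in it. Rows were counted as higher or lower in the resistant line as deposited. For single genes and lists the difference was log2((resistant + 1)/(parental + 1)), with a pseudocount of 1 and no filter on low values. No statistical test between the lines was made, because each group is 1 sample. Rows listed at 0 in 1 line and above 0 in the other were counted separately.

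The genes named in the text follow a rule. Among rows with a gene symbol, leaving out LOC placeholder names, and with a value of at least 10 in the higher line, the 10 largest increases and the 10 largest decreases on the log2(value + 1) scale were taken, then up to 4 members of each list with the largest absolute difference under the same filter, then ABCB1, ABCC1, ABCG2, MVP, TOP2A and TOP2B if listed. Of the terms, the 10 with the smallest p-values were taken. Other members of small lists, further genes in the accounts of chromosome 14 and of rows at 0, and terms set beside the lists, were named after their values were seen. Values of some genes that the rule takes are not reported here. The 20 gene lists covered ABC transporters and vault genes, topoisomerases and DNA repair, p53 targets, BCL2 family and caspases, antioxidant and carbonyl-reducing enzymes, B cell identity, germinal centre and plasma cell genes, MHC and antigen processing, NF-kB and cytokines, interferon-stimulated genes, MAPK and PI3K-AKT, Notch and Wnt, cell cycle, adhesion and matrix, lysosome, glycolysis and hypoxia, chromatin regulators, and markers of T and NK cells, of myeloid cells and of stromal, endothelial and epithelial cells. Together they had 100 distinct rows in the table, matched by symbol and then by gene ID. For lists with at least 3 rows, the median log2 difference was ranked among 10000 random lists of the same size from the same rows, matched on mean abundance in 10 bins. The lists, the naming rule, the counts and most other settings tried were set before the data were examined.

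Runs of rows in 1 direction were sought after the data were examined. Rows were ordered by position on each chromosome, stretches were scored for a share of 95% in 1 direction against the share over all rows, and runs with a score above 9.48, the 95th percentile of the highest scores in 1000 shuffles of the directions over the rows, were kept. The chromosome 14 stretch was extended from RUNDC3B while the next row had a log2 difference above 1.5. To hold abundance or genomic length fixed, the directions were also shuffled 1000 times among rows of the same bin only, with 10 bins of the mean abundance or of the length.

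The procedures were tested on simulated data for the comparison of the resistant with the parental line, with 1729 rows. The 50 genes raised 2-fold had a median estimated log2 difference of 0.86 and the 50 raised 4-fold 1.84. Over the 100 genes changed in either direction at each fold size, 100% had the right sign. A list of 8 genes raised 2-fold ranked at percentile 100, and 94% of unchanged lists lay between the 5th and the 95th percentile. A planted run of 40 lower rows was recovered with 40 rows, and 0 other runs were found. No run of higher rows was planted. Most simulated rows were unchanged and the noise was small, which makes a right sign easy to reach. The real rows were selected for being different, so the simulation does not show how the list percentiles behave among them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

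Results were also computed with a 4-fold threshold, a minimum value of 1 in the higher line, a mean of at least 5, upper-quartile scaling with a 2-fold threshold, a 2-fold threshold on the log2(value + 1) scale, each gene symbol once with LOC placeholder names left out, a limit of 0.1 for detection, at least 1 in the other line, pseudocounts of 0.1 and 5, centring on the median of all rows, unmatched random lists, the deposited log2 fold change, and terms with at least 10 genes. Other settings were added after the data were seen: counts and lists without the rows in chromosome runs and limits of 0.001 and 0.05 on the deposited p-value of terms. Limits on an adjusted p-value were not run because the tables used here hold none.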

Results

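RNA sequencing compared CLBL-1, a canine diffuse large B-cell lymphoma cell line, with CLBL-1 8.0, a doxorubicin-resistant form of CLBL-1 that was kept in medium with 8 µM doxorubicin. Doxorubicin is an anthracycline drug that intercalates into DNA and traps topoisomerase II on it. The comparison asked which transcripts differed in abundance between the resistant line and the parental line. Each line was represented by 1 sample and 1 abundance value per gene, so no difference given here has a replicate check. The depth of the libraries is unknown because the values are not read counts, and whether they are FPKM or TPM is not stated. Whether the drug was withdrawn before RNA was extracted is not stated either, so drug exposure and resistance were not separated by the design. The comparison table held 1729 rows, a selection of genes made by the authors. All 1729 rows had a larger value of at least 5.01 and differed at least 1.59-fold between the lines, apart from 9 rows in which 1 line was listed at 0 and no fold was computed. Genes without a row were not analysed here.

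The resistant line had far higher levels of a group of neighbouring genes on chromosome 14. Among them, RUNDC3B was 116-fold higher, DBF4, the regulatory subunit of the CDC7 kinase that starts DNA replication, was 51.7-fold higher, and SRI, which encodes the calcium-binding protein sorcin, was 48.0-fold higher. In the other direction, RAC2, a small GTPase of blood cells, was at 0.141 in the resistant line against 105 in the parental line, with a log2 difference that depends on how the low value is treated: -9.55 as deposited, -6.54 with a pseudocount of 1 and -4.42 with a pseudocount of 5. FERMT3, the integrin activator kindlin-3, was 46.5-fold lower in the resistant line as deposited. Its log2 difference also depends on the low value: -5.54 as deposited, -4.92 with a pseudocount of 1 and -3.71 with a pseudocount of 5. All 5 listed interferon-stimulated genes were lower in the resistant line. Of 7 listed genes of the NF-kB and cytokine list, 6 were higher, against 65.2% of all 1729 rows. Related terms of the authors' deposited table did not all lean in these directions. Whole stretches of chromosomes shared a direction, with 214 of 227 listed rows of chromosome 6 higher and 45 of 46 listed rows of chromosome 36 lower in the resistant line.

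Of the 1729 rows, 1127 (65.2%) were higher and 602 were lower in the resistant line. For upper-quartile scaling, the parental values were multiplied by 1.25, which equalised the upper quartiles over listed rows above 0 in both lines. With a 2-fold difference also required on the log2(value + 1) scale, 216 rows were higher and 533 were lower. The higher share was then 28.8%. The same 2-fold requirement without this scaling gave 416 higher and 249 lower rows. The upper quartile of the resistant line was 1.25 times that of the parental line, a shift of 0.32 on the log2 scale. The smallest absolute log2 fold in the table was 0.67, so this scaling alone could turn no row, and the 216 and 533 rows reflect which rows passed the 2-fold limit after the shift. The median log2 difference over all rows was 0.73. Because the rows were selected for being different, neither value measures a shift of the whole transcriptome. Centring on this median lowers every difference by 0.73, so a sign that turns with it shows only that the difference was positive and below 0.73. Log2 differences below are log2((resistant + 1)/(parental + 1)), which understates the difference of genes with low values.

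Besides the chromosome 14 genes, the 10 genes with the largest increases under the naming rule included CAPZB, a subunit of the actin-capping protein, at 201 in the resistant line against 3.78 in the parental line. LPAR6, a receptor for lysophosphatidic acid, was at 16.7 against 0.103, and the zinc finger gene ZNF74 was at 13.3 and listed at 0 in the parental line. The position given for LPAR6, chromosome 22 from 3110797 to 3112973, lies inside RB1 on the opposite strand, and RB1 was itself at 45.7 against 21.2, so reads of these genes may not have been separable. Among the 10 largest decreases, RAC2 was at 0.141 in the resistant line against 105 in the parental line. SLPI, a secreted inhibitor of serine proteases, was at 0.194 against 97.8. PTPRCAP, which binds the leukocyte phosphatase CD45, was at 1.55 against 80.0, and FERMT3 was at 1.81 against 84.0. PDE1A, a calmodulin-dependent phosphodiesterase, was at 0.0706 against 31.3, and WDR41 was at 0.423 against 21.2. MZB1, an endoplasmic reticulum cofactor of antibody assembly in B cells and plasma cells, was at 0.281 against 18.7. NLRC3, a member of the NLR family, was listed at 0 in the resistant line against 13.7, and IFGGB2, described in the table as an interferon-inducible GTPase, was at 0.532 against 20.1. Under the naming rule, the most extreme row in each direction is uncertain. TUBB4B, a beta-tubulin gene, has 2 rows with the same resistant-line value of 889.6 but parental values of 1.77 on chromosome 1 and 1833 on chromosome 9. RPL18, a ribosomal protein gene, also has 2 rows, both at 1.84 in the resistant line and at 3359 on chromosome 1 and 8.92 on chromosome X in the parental line. The TUBB4B row on chromosome 1 and the RPL18 row on chromosome X lie on another chromosome than the genes of those names in the reference table. The identity of the row with the largest increase under the rule is therefore uncertain, and the TUBB4B row on chromosome 9 was lower in the resistant line.

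**Figure D1:**
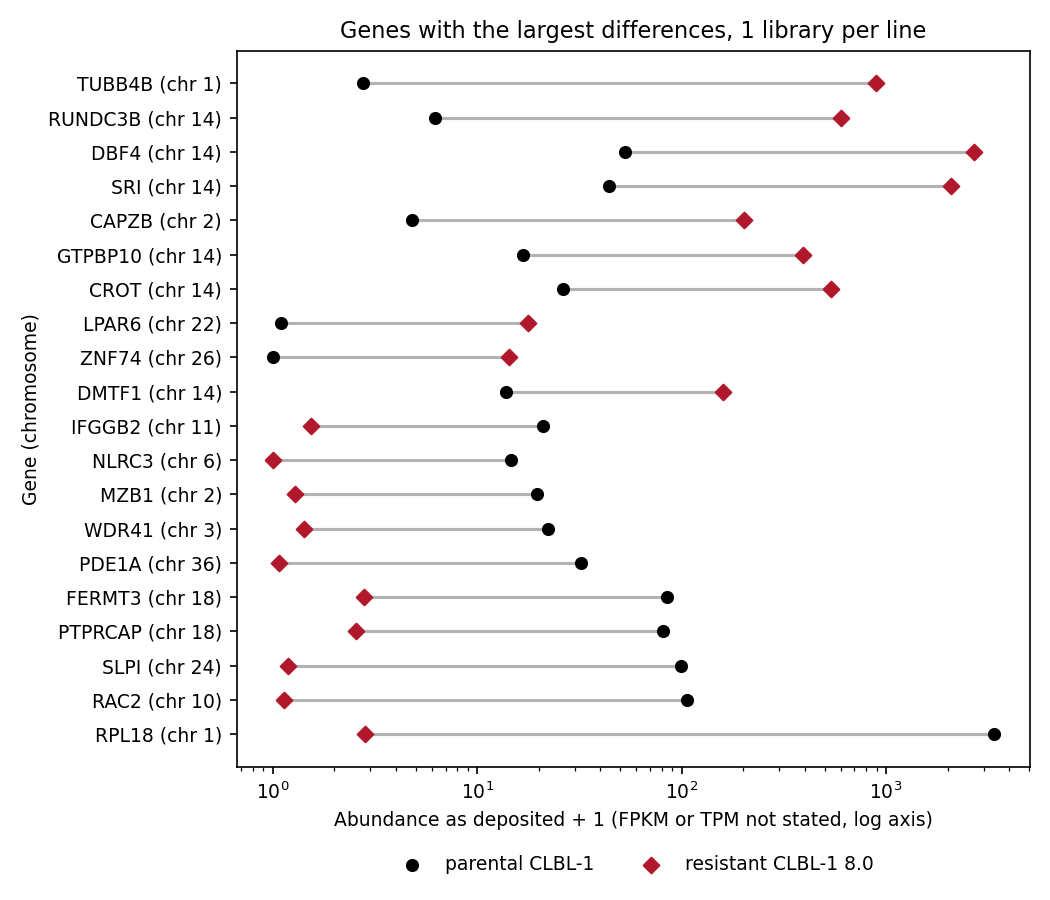
Abundance in the parental line (black circles) and the resistant line (red diamonds) of the 10 genes with the largest increases and the 10 with the largest decreases, plotted as the deposited value plus 1 on a log axis, with 1 library per line. RAC2 lies at 105 in the parental line and 0.141 in the resistant line, and RUNDC3B at 5.19 and 604; the rows shown for TUBB4B and RPL18 repeat a value of another row of the same symbol, and the TUBB4B row shown lies on another chromosome than the gene of that name in the reference table.

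On chromosome 14, 12 consecutive rows between 13.3 and 17.0 Mb (coordinates as deposited; CanFam3.1 per the submitters' processing notes) had log2 differences from 2.58 to 6.61, with a median of 3.55. This stretch was delimited after the values were seen. DMTF1, a Myb-like transcription factor that binds cyclin D (gene ID 475217, positions 13336316 to 13378231), was at 159 in the resistant line against 12.9 in the parental line. CROT, a peroxisomal carnitine octanoyltransferase (gene ID 482283, 13475130 to 13533130), was at 537 against 25.2. RUNDC3B (gene ID 482285, 13764583 to 13933025) was at 604 against 5.19. DBF4 (gene ID 475219, 13983832 to 14019917) was at 2693 against 52.1, and SRI (gene ID 475220, 14257375 to 14274816) was at 2079 against 43.3. GTPBP10, a GTPase of mitochondrial ribosome assembly (gene ID 100683980, 16247715 to 16274823), was at 393 against 15.7. CLDN12, a claudin (gene ID 608397, 16286030 to 17007482), was at 111 against 10.7. The next rows outside the stretch had log2 differences of 0.67 and 0.72, and the other 34 rows of chromosome 14 had a median of 1.01. High differences on this chromosome were not confined to the stretch: KBTBD2 (positions 44941116 to 45187687), at 902 against 114 with a log2 difference of 2.97, lay within its range, and HEPACAM2 (18691326 to 18742195), at 5.67 against 0.124 with 2.57, lay just below it. In the gene order of the reference table, 21 protein-coding genes lie from DMTF1 to CLDN12, of which 8 had a row. ABCB4 and ABCB1, which encodes the drug efflux pump P-glycoprotein, lie there between CROT and RUNDC3B, and neither was in the rows analysed here.

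**Figure D2:**
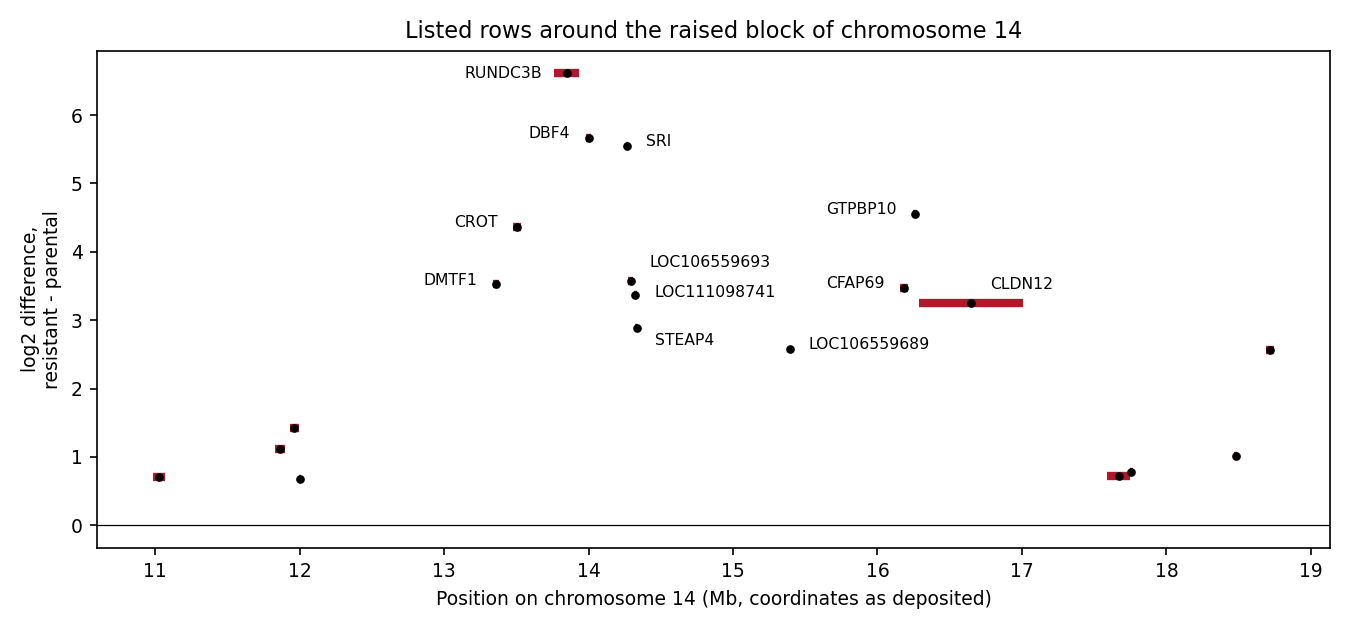
Log2 difference between the resistant and the parental line against position on chromosome 14 in Mb for the listed rows in and around the raised stretch. Each red bar spans a row's start to end and the black point marks its middle. The 12 named rows from DMTF1 to CLDN12 lie between 2.58 and 6.61, and the rows next to them lie at 0.67 and 0.72.

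The lists of genes tied to doxorubicin response had few members in the table. Of 23 ABC transporters and vault genes, 2 were listed and both were higher in the resistant line: MVP, the major vault protein, at 27.9 against 14.5, and ABCA3 at 8.81 against 3.98. ABCB1, ABCC1, ABCG2, TOP2A and TOP2B had no row. Of 56 topoisomerase and DNA repair genes, 1 was listed, TOP3A, at 20.2 in the resistant line against 45.7. These listed genes all lie in chromosome runs that share their direction. MVP and ABCA3 lie on chromosome 6, where 214 of 227 rows were higher, and TOP3A lies in the lower run of chromosome 5. Of 32 p53 target genes, 4 were listed, 3 higher and 1 lower, with a median log2 difference of 1.02. The cell cycle inhibitor CDKN1A was at 113 against 49.4 and the pro-apoptotic PMAIP1 at 35.8 against 13.7. The list of BCL2 family genes, caspases and inhibitors of apoptosis had 6 of 40 members listed, 3 higher and 3 lower, with a median of -0.037. In it, the survival gene BCL2L1 was at 11.7 against 3.69, whereas BIRC5, which encodes survivin, was at 81.5 against 297 and the death ligand TNFSF10 at 34.1 against 67.4. Antioxidant, glutathione and carbonyl-reducing enzymes had 7 of 59 members listed, 3 higher and 4 lower. Their median of -1.07 and mean of 0.037 differed in sign, and the median was -0.061 without the 1 member in a chromosome run. CBR4, a carbonyl reductase, was at 12.8 against 0.889 and the aldo-keto reductase AKR1B1 at 273 against 110. The quinone reductase NQO1 was at 137 against 324, and ALDH3A2, a fatty aldehyde dehydrogenase, at 11.8 against 31.4.

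Among B cell identity and receptor signalling genes, 4 of 57 were listed, 1 higher and 3 lower in the resistant line, with a median of -1.13. The larger B cell receptor signalling term of the authors' deposited table was split, with 6 of 11 genes higher. VAV1, an exchange factor for Rac GTPases, was at 2.27 against 14.5, the kinase subunit PIK3CD at 3.34 against 10.1, and the tetraspanin CD37 at 26.6 against 50.4. CD81, another tetraspanin, was at 159 against 98.9, and its log2 difference of 0.68 became -0.051 when centred on the median of all rows. Germinal centre and plasma cell genes had 2 of 32 members listed, S1PR2, a sphingosine-1-phosphate receptor, at 19.1 against 7.36 and MZB1, lower as given above. Of 39 genes of MHC and antigen processing, 7 were listed, 3 higher and 4 lower, with a median of -0.95 and a mean of -0.29. The lower members belonged to the class I pathway: NLRC5, its transcriptional activator, was at 9.71 against 32.9, the class I heavy chain DLA88 at 206 against 457, its partner B2M at 797 against 1550.0, and the trimming peptidase ERAP1 at 34.8 against 68.4. Of the higher members, DLA-DQA1 and HLA-DRB1 encode class II chains, at 373 against 190 and at 1014 against 567, and CTSS, a cathepsin, was at 60.4 against 33.0. Values of the MHC genes are uncertain because near-identical family members can share reads.

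All 5 of the 48 interferon-stimulated genes that were listed were lower in the resistant line, with a median of -2.16. The antiviral membrane protein BST2 was at 7.09 against 49.0 and the exonuclease ISG20 at 1.88 against 11.9. TMEM173, which encodes the DNA-sensing adaptor STING, was listed at 0 against 8.34, and OAS1 was at 1.53 against 7.18. Related terms of the authors' deposited table went both ways, against 65.2% higher among all rows. Defense response to virus had 5 of 14 genes higher and negative regulation of viral genome replication 3 of 7, while RIG-I-like receptor signalling had 9 of 12 higher. NF-kB components and targets, cytokines and chemokines had 7 of 62 members listed, 6 higher and 1 lower, with a median of 1.27. The chemokine CCL5 was at 43.1 against 5.71, the receptor subunits IL10RA and IL2RA at 19.6 against 2.76 and at 81.8 against 25.03, and the inhibitor NFKBIA at 26.3 against 10.3. CXCL10, an interferon-induced chemokine, was the lower member, at 7.80 against 36.8. Without the 2 members in chromosome runs, IL10RA and CXCL10, the remaining 5 were higher. Larger related terms of the authors' deposited table did not lean this way: 7 of 15 genes of TNF signalling, 14 of 25 of chemokine signalling and 9 of 15 of Toll-like receptor signalling were higher, against 65.2% of all rows, while response to cytokine had 5 of 6 higher. Of 81 MAPK and PI3K-AKT genes, 13 were listed, 8 higher and 5 lower, with a median of 1.03. The ERK phosphatase DUSP6 was at 18.8 against 3.38, the AP-1 subunit JUND at 316 against 104, the regulatory subunit PIK3R2 at 21.2 against 6.71, and the JNK kinase MAPK8 at 48.2 against 21.4.

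The cell cycle list had 11 of 62 members listed, 4 higher and 7 lower, with a median of -0.71. The lower members were mitotic genes, among them AURKB at 61.9 against 170, BIRC5, CCNB1 at 162 against 271 and CENPA at 50.3 against 95.5. Of the 4 higher members, 3 restrain the cell cycle: CDKN2B at 116 against 41.5, CDKN1A and RB1. The fourth, CCNE2, was at 17.5 against 9.76. Glycolysis and hypoxia genes had 4 of 44 members listed, all 4 lower, with a median of -0.88, including the lactate transporter SLC16A1 at 30.8 against 67.7, PDK1 at 62.8 against 116 and the phosphofructokinase PFKL at 18.2 against 32.1. PDK1 lies in the lower chromosome run on chromosome 36, and the 3 members outside the runs had a median of -0.88. Lysosome and acidification genes had 10 of 53 members listed, 8 higher and 2 lower, with a median of 0.78. The channel MCOLN2 was at 44.4 against 10.5, the cholesterol transporter NPC1 at 22.1 against 8.12, the hydrolase GUSB at 72.3 against 29.5 and LAMP3 at 32.4 against 14.9. Adhesion and matrix genes had 5 of 84 members listed, 3 higher and 2 lower, with a median of 1.06. CD44, a hyaluronan receptor, was at 18.4 against 7.82 and the protease inhibitor TIMP1 at 401 against 192, while the laminin chain LAMC1 was at 47.6 against 78.9.

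The remaining lists had members in both directions or a single listed member. Notch and Wnt genes had 4 of 57 members listed, 2 higher and 2 lower, with AXIN1 at 57.8 against 20.9 and RBPJ at 11.5 against 19.3. Their median of 0.11 became -0.62 when centred on the median of all rows and -0.63 without the 1 member in a chromosome run. Chromatin regulators had 5 of 59 members listed, 3 higher and 2 lower, with CBX8 at 26.5 against 13.5, UHRF1 at 72.0 against 117 and CREBBP at 20.9 against 12.6. The chromatin median of 0.69 became -0.043 when centred and -0.57 without the 2 members in chromosome runs, and CREBBP itself became -0.043 when centred. Markers of other cell types were checked as well. For T and NK cells, 6 of 41 markers were listed, 3 higher and 3 lower, with TRAT1 at 20.6 against 2.72, GZMA at 47.1 against 23.5 and EOMES at 27.7 against 47.3. The others had lower values: ICOS was at 7.67 against 2.28, THEMIS at 0.0989 against 5.69 and PRF1 at 1.07 against 6.67. The median of these markers was 0.11 and became -0.62 when centred and 0.97 over members with a mean value of at least 5. Of 36 myeloid markers, FCER1G was listed, at 14.01 against 7.74, and of 29 stromal and epithelial markers EPCAM was listed, at 2.07 against 5.26.

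**Figure D3:**
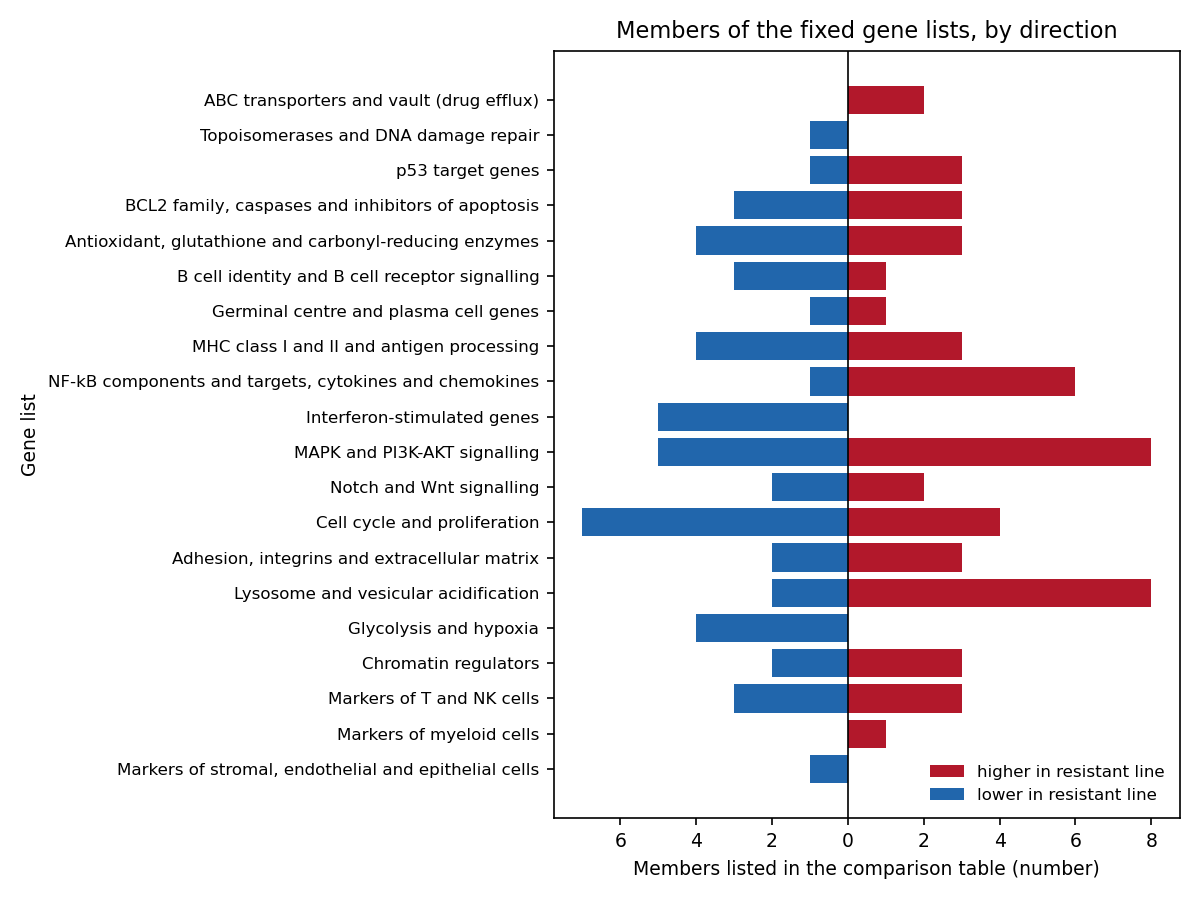
Number of members of each of the 20 gene lists that were listed in the comparison table, to the right for members higher in the resistant line (red) and to the left for members lower in it (blue). The interferon-stimulated list has 0 higher and 5 lower members, and the NF-kB and cytokine list has 6 higher and 1 lower.

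Against 10000 random lists of the same size drawn from the same rows and matched on mean abundance, the interferon-stimulated median lay at percentile 0.03, the B cell median at 1.84, the glycolysis median at 7.88 and the cell cycle median at 12.9. The NF-kB and cytokine median lay at percentile 99.7, the MAPK and PI3K-AKT median at 98.1 and the p53 target median at 87.7. The MAPK and PI3K-AKT list did not lean higher by count, with 8 of 13 members higher against 65.2% of all rows. Its mean log2 difference was 0.51, and its percentile reflects the size of its middle member. The lysosome median lay at percentile 63.3. The other ranked lists were split evenly or nearly so, and their medians and percentiles hang on 1 member: the antioxidant median at 0.87, the MHC median at 1.5, the adhesion median at 93.5, chromatin at 39.6, Notch and Wnt at 32.6, T and NK cell markers at 28.6 and the BCL2 family at 21.9. The B cell and p53 target lists had 4 listed members each, split 3 to 1, so their percentiles also depend on few genes. The mean log2 differences of the antioxidant, MHC, adhesion and chromatin lists were 0.037, -0.29, 0.38 and 0.22. All these percentiles describe 2 libraries and rank each list within the authors' selection, not within all expressed genes.

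Several chromosomes had rows mainly in 1 direction, a pattern followed up after the values were seen. Chromosome 6 held 227 rows, 13.1% of the table, and 94.3% of them were higher in the resistant line. On chromosome 14, 43 of 46 rows were higher. Chromosome 36 had 97.8% of its rows lower and chromosome 32 had 25 of 31 rows lower. Of these, 172 of the 227 rows of chromosome 6 and 39 of the 46 rows of chromosome 14 were above the median log2 difference of all rows. Chromosome 5 was divided: from 9.72 to 21.5 Mb, SIAE to SIK2, all 32 rows were higher, and from 21.9 to 57.4 Mb, ending at TNFRSF14, 84 of 89 rows were lower. On chromosome 4, 32 of 34 rows from 36.04 to 62.2 Mb, MXD3 to MOCS2, were lower. In all, 7 runs with scores above the 95th percentile of 1000 shuffles of the directions held 488 rows, and 95.7% of those rows had the direction of their run. The runs were sought with a score built for a share of 95%, so this share follows from how they were chosen. The runs on chromosome 14, with a score of 13.9, and on chromosome 5 from 9.72 Mb, with 12.1, stayed below the highest score of any shuffle, 14.1, and the other 5 runs exceeded it. Members of the gene lists that lie in these runs include MVP, ABCA3, TOP3A, AURKB, IL10RA, CXCL10, GUSB, MCOLN2, PDK1, AXIN1 and CREBBP.

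**Figure D4:**
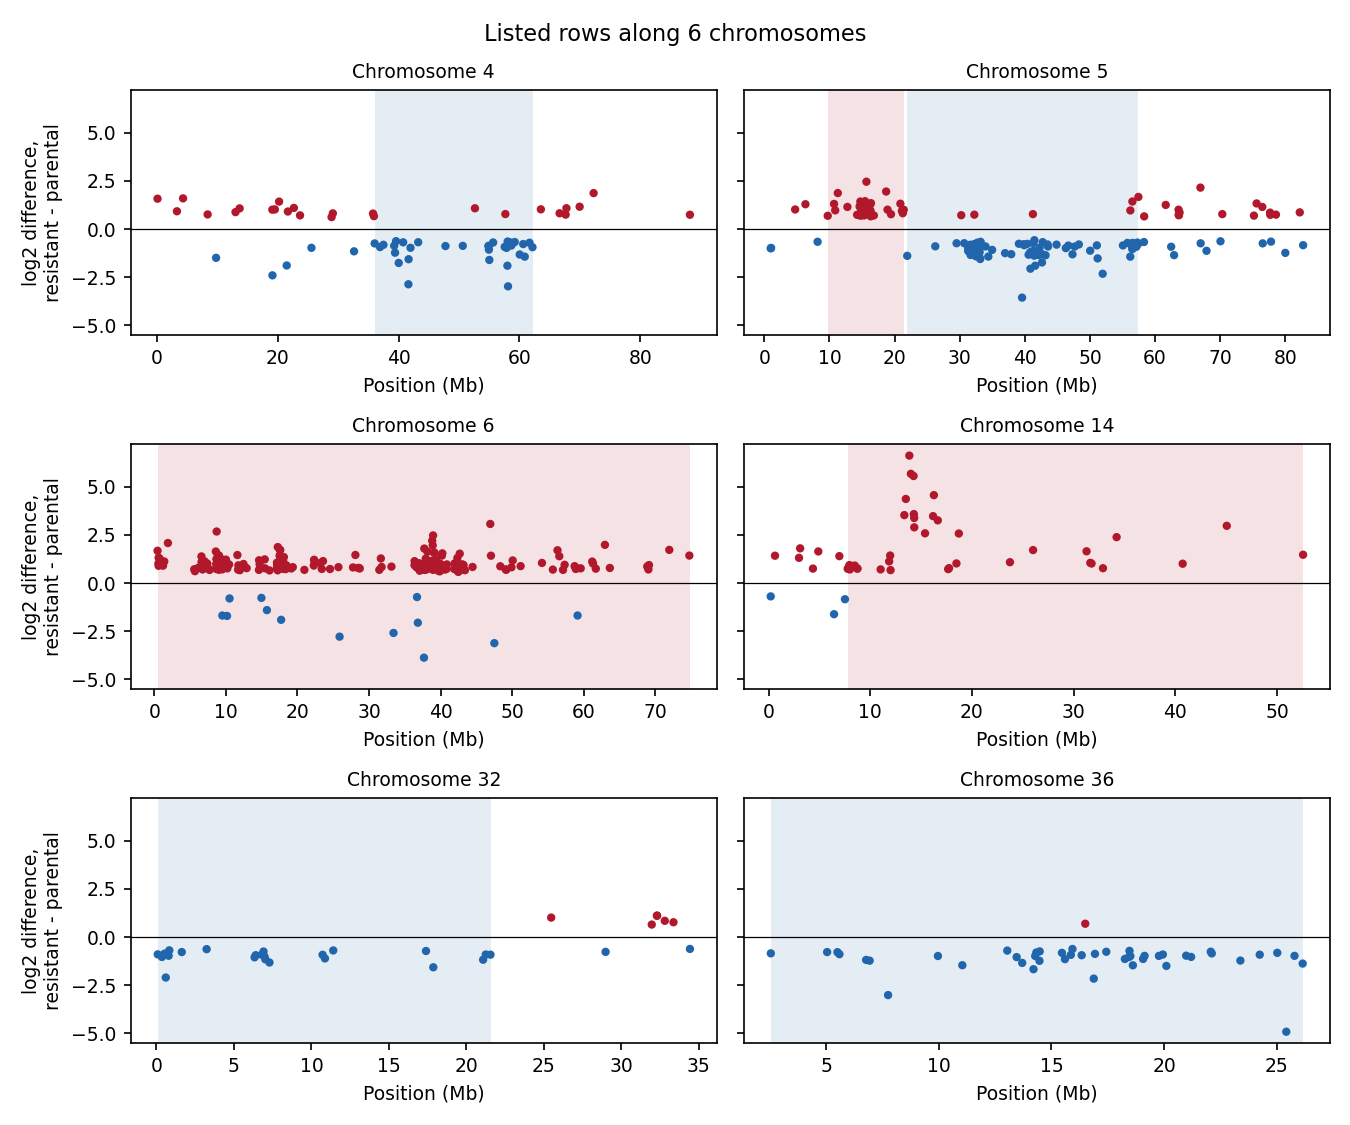
Log2 difference between the resistant and the parental line of each listed row against its position in Mb on chromosomes 4, 5, 6, 14, 32 and 36, with red points for rows higher and blue points for rows lower in the resistant line; shaded stretches are the 7 runs. On chromosome 6, 214 of 227 points lie above 0, and on chromosome 36, 45 of 46 lie below 0.

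In 9 rows 1 of the lines was listed at 0. In the resistant line these included NLRC3, TMEM173, the glutathione S-transferase theta-1-like gene LOC477558, listed at 0 against 34.8 in the parental line, and the tRNA genes TRNAK-CUU and TRNAE-CUC. The rows for both tRNA genes lie on another chromosome than the genes of those names in the reference table, so their identity is uncertain. In the parental line, ZNF74, GPR151 and LOC111092726, a C-type lectin domain gene, were listed at 0, against 13.3, 5.84 and 14.03 in the resistant line. Counting values under 0.1 as not detected gave 19 such rows, 13 in the resistant line and 6 in the parental line. A listed 0 may be a failed estimate, so no fold is given for these genes.

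The authors' deposited table of ontology and pathway terms held 168 terms, with a highest p-value of 0.0997. Golgi apparatus had the smallest p-value in the authors' deposited table, 0.000151, with 45 of its 65 genes higher and 20 lower in the resistant line. Endocytosis followed in the authors' deposited table, with a p-value of 0.00018 and 31 of 37 genes higher. The authors' deposited table also gave intracellular protein transport, with a p-value of 0.000397 and 19 of 30 genes higher, and cytosol, with 0.000684 and 72 of 106 genes higher. Fc epsilon RI signalling had a p-value of 0.000618 in the authors' deposited table, and 9 of its 15 genes were lower. Among disease pathways, the authors' deposited table gave p-values of 0.00045 for HTLV-I infection, with 24 of 37 genes higher, 0.00124 for colorectal cancer and 0.00197 for pancreatic cancer, each with 9 of 14 higher, and 0.00337 for pathways in cancer, with 36 of 49 higher. Apoptosis had a p-value of 0.00247 in the authors' deposited table, and 8 of its 13 genes were higher. Of other terms in the authors' deposited table that match a list, named after their counts were seen, p53 signalling had 7 of 12 genes higher, MAPK signalling 20 of 28, the KEGG lysosome term 16 of 19 and natural killer cell cytotoxicity 6 of 15. Part of the term genes lie in chromosome runs: 20 for Golgi apparatus and 8 each for endocytosis, MAPK signalling and the KEGG lysosome term. Outside the runs these 4 terms had, in that order, 31 higher and 14 lower, 25 and 4, 17 and 3, and 10 and 1. The terms were chosen on these samples, so the counts of genes in each direction are not independent evidence, and 65.2% of all rows were higher to begin with. The tool, background and adjustment behind these p-values are not stated.

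Overlapping genes limit single values. Of the 73 genes named by rule, the spans of 27 overlap another gene in the reference table or another row. Exons and strand handling were not examined, so whether these genes share reads with the neighbour is uncertain. These included RAC2, IFGGB2, CDKN2B, DMTF1, RUNDC3B, SRI, SLC16A1, FERMT3, CD37, BCL2L1, CBR4, IL2RA, CAPZB, LPAR6, CXCL10, PDK1, RBPJ, IL10RA, AURKB, ALDH3A2, PIK3CD, NLRC3, AXIN1, NPC1, CCL5 and TIMP1.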

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

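The alternatives without the rows in chromosome runs and with limits on the deposited p-value of terms were chosen after the results were seen, and the others were planned. Counts of rows stayed within 1.5 times of the main counts with a mean of at least 5 (978 higher and 525 lower), a minimum value of 1 in the higher line, which removed no row, each symbol once with LOC placeholder names left out (966 and 504) and without the chromosome runs (836 and 405). A 4-fold threshold left 99 higher and 80 lower rows, a 2-fold threshold on the log2(value + 1) scale 416 and 249, and upper-quartile scaling with that threshold 216 and 533; the thresholds lower the counts by construction, and upper-quartile scaling lowers each log2 fold by 0.32. With values under 0.1 counted as not detected, 19 rows in place of 9 were detected in 1 line. Centring on the median of all rows lowers each difference by 0.73, and with it list medians were 0.29 for p53 targets, -0.77 for the BCL2 family, -1.80 for antioxidant enzymes, -1.86 for B cell genes, -1.68 for MHC, 0.54 for NF-kB and cytokines, -2.89 for interferon-stimulated genes, 0.30 for MAPK and PI3K-AKT, -1.44 for the cell cycle, 0.32 for adhesion, 0.046 for the lysosome and -1.61 for glycolysis, and the sign turned for Notch and Wnt at -0.62, chromatin regulators at -0.043, T and NK cell markers at -0.62, CD81 at -0.051 and CREBBP at -0.043. With a mean of at least 5, the BCL2 family was at -0.63, antioxidant enzymes at -0.061, chromatin regulators at 0.059 and T and NK cell markers at 0.97, because fewer members entered. A pseudocount of 5 put the interferon-stimulated median at -1.29, since a larger pseudocount shrinks differences of low values. Without the chromosome runs, the antioxidant median was -0.061, and Notch and Wnt at -0.63 and chromatin regulators at -0.57 turned sign. A pseudocount of 0.1 moved none of the 15 list medians by 0.58 or more, and unmatched random lists left all 15 percentiles on the same side of 50. Of the 73 named genes, pseudocounts of 0.1 and 5 moved 11 and 21 by at least 0.58, none with a change of sign. The deposited log2 fold change, which has no finite value for NLRC3 and ZNF74, moved 12 and left 59 within 0.58, also with no change of sign. Among them, RAC2 went from -6.54 to -8.77, -4.42 and -9.55, FERMT3 from -4.92 to -3.71 with a pseudocount of 5 and -5.54 as deposited, and RUNDC3B from 6.61 to 5.90 with a pseudocount of 5. Terms with at least 10 genes numbered 90, those with a deposited p-value under 0.001 numbered 6 and those under 0.05 numbered 97. The planned limits on an adjusted p-value were not run. With 1 library per line no library could be left out, and no paired analysis was possible because each line has 1 sample. Depth is unknown, so how far counting error reaches into genes with low values was not measured.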

Other observations

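All tests of explanations in this part were chosen after the results were seen, except the comparison of spreads for the chromosome runs, which was set before that spread was computed. The genes and gene groups in the next 2 paragraphs were also chosen after their values were seen.

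Some single genes outside the lists are given as values only. DCK, the kinase that activates deoxycytidine analogue drugs, was at 73.0 in the resistant line against 241 in the parental line. ADA, adenosine deaminase, was at 6.20 against 22.7, and NT5E, the ectoenzyme CD73 that makes adenosine, was at 28.7 against 7.96. HCLS1, an actin regulator of blood cells, was at 0.120 against 13.8, DOCK8, an exchange factor for CDC42, was at 1.22 against 14.8, and STAT4 was at 0.523 against 6.31. S100A4, a calcium-binding protein linked to cell motility, was at 1579 against 586.

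The 3 immunity-related GTPase genes listed, IFGGB1, IFGGB2 and IFGGC1, lie close together on chromosome 11 and were all lower in the resistant line, with a median log2 difference of -3.70, and their reads can be shared between family members. Of 9 ribosomal protein genes, leaving out RPL18, 8 were lower, with a median of -0.78. The exception, RPS25, at 4509 against 2785, lies in the higher run of chromosome 5, and outside the runs all 5 were lower. Of 6 mitochondrial ribosomal protein genes, 5 were lower, with a median of -0.95, and of the 3 outside the runs 1 was higher and 2 were lower. Of 31 zinc finger genes with ZNF names, 25 were higher, with a median of 0.83. Outside the runs 13 were higher and 6 lower, close to the 67.4% higher among all rows outside the runs.

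The stretch of 12 raised rows on chromosome 14 surrounds the place of ABCB1 in the reference gene order. A scaling difference between the libraries would move all rows alike, yet the median log2 difference of the 1717 rows outside the stretch was 0.73, against a lowest value of 2.58 inside it. Reads shared between overlapping genes stay open for 9 of the rows, while 3 rows, CROT, DBF4 and GTPBP10, were found to overlap no other row and no other reference gene. One equal gain of DNA copies was not decided either: the deposited log2 folds of these 3 rows ranged over 1.28, between the limits set for the test, and those of the 7 rows with a parental value of at least 5 ranged over 3.50, though most of them overlap other genes. A gain of DNA, equal or unequal along the stretch, or joint activation of the region in the drug-resistant line may underlie it as a hypothesis, and DNA copy number and the genes without a row were not analysed here.

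Of the 7 runs of rows in 1 direction along chromosomes, 5 had scores of at least 23.1, above the highest of 1000 shuffles of the directions, 14.1. Scores of the other 2, 13.9 on chromosome 14 and 12.1 on chromosome 5 from 9.72 Mb, stayed below 14.1. Both lay above 9.48, the 95th percentile of the highest shuffle scores, as every kept run had to. Chance order was argued against for the 5 runs. It was not decided for these 2, whose scores lay between the limits set for the test. The score counts directions only, so the size of the differences did not enter it. Abundance and genomic length were argued against for the 5 runs, since shuffles among rows of like abundance gave scores of at most 11.9 and shuffles among rows of like length at most 12.05, while GC content was not tested. Gains and losses of chromosome segments in one of the lines are a candidate explanation, and they would give differences of more even size inside the runs than elsewhere. The interquartile range of the absolute log2 fold was 0.478 in the runs and 0.523 outside them, a ratio of 0.914, which lay between the limits set beforehand. Without the run on chromosome 14, the range in the runs was 0.447 and the ratio 0.854, also between these limits. The authors' selection cut both spreads, since no row had an absolute log2 fold under 0.67 and smaller copy-number effects would not be listed, so this comparison decides nothing, and a copy-number cause and regional regulation cannot be told apart here.

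The resistant-line values of TUBB4B and RPL18 each appear in 2 rows. That values of the resistant line were looked up by gene symbol may be the reason, but this idea came from the same pairs: both symbols with more than 1 row, 2 of 2, held 1 value for the resistant line and different values for the parental line, and 0 pairs shared a parental value. There is no further pair to test it on, so it stays open. The TUBB4B row on chromosome 1 and the RPL18 row on chromosome X lie on another chromosome than the reference gene. Which row each repeated value was measured on was not tested, and no biological explanation was tested.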
